A study of Rattus norvegicus with 24 samples.

How the data were processed

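RNA sequencing measured gene expression in primary rat cardiac fibroblasts from animals of 4 ages: 0-3 days, 3-4 weeks, 10-13 weeks and 20 months. Per the labels, the cells were cultured for 24 hours in DMEM with 5.5 mM glucose, called normal glucose here, or 33 mM glucose, called high glucose. Each of the 8 groups held 3 libraries, 24 in all. The series gives 1 table, in which the authors list a count and an FPKM value (fragments scaled by gene length and by total) for each of 30957 genes in each library. The deposited counts are whole numbers without normalization. The deposited FPKM values equal the counts divided by a fixed length per gene and by each library's own total. Per the submitters' processing notes, HISAT2 2.0.4, StringTie 1.3.0, edgeR and the genome build Rnor_6.0 were used. The notes give no role for each tool and no annotation release, strandedness or filter. Gene positions are those of the deposited table, on Rnor_6.0.

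The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passed a filter (filterByExpr by group, minimum count 10, minimum total 15, at least 3 libraries), which left 13806 genes. A further 11647 of the genes in the table had no count in any library. Library sizes were scaled by TMM, and levels are given as CPM, the usual per-library scaling of counts by the TMM-scaled library size, except for the summed levels of cell type markers, which use the plain totals. One model with a mean per group was fitted to all 24 libraries by the robust quasi-likelihood method. The comparisons were high against normal glucose at each age, the mean of these 4 effects, the interaction of glucose with age, the effect of age within each glucose level (F tests), and 4 pairs of ages in normal glucose. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p values of genes come from edgeR unless another tool is named, and tests of 2 groups are two-sided. Log2 changes are given with a standard error (SE), taken as the absolute log2 change divided by the square root of the quasi-likelihood F statistic. Levels are given with the standard deviation (SD) of 3 libraries.

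The labels number the libraries of each group 1 to 3 without saying whether equal numbers share an animal or a cell preparation. After group means were taken off, libraries with the same number at the same age correlated across genes at 0.2 to 0.67, whereas differently numbered libraries of an age correlated at -0.07 at most. Taking off the mean makes a library's covariances with the 3 libraries of the other glucose level sum to 0. A positive value for the same number thus forces negative ones elsewhere, but nothing forces the positive value onto the same number. Same-numbered libraries of different ages correlated at -0.22 to 0.26. Genes are not independent replicates, so these correlations carry no test. The main test of glucose was the unpaired one. A fit with the replicate number as a block within each age was also written before the data were examined, and same-numbered cultures are called pairs. The glucose results at each age lead with this paired fit, a choice made after the correlations above were seen in the same data. Genes named from it thus rest on equal numbers marking pairs, which the labels do not state. Nothing in the labels says that the samples are separate animals or separate cultures, so p values measure the spread between samples. The labels also give no strain or passage number at each age, so a difference in these between the ages is not separated from age in any age comparison.

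The comparisons, tests, lists of genes, other settings to try and the rule for naming genes were written before the data were examined. The rule takes up to 10 called genes per direction with the largest changes, a mean log2 CPM of at least 1, groups that do not overlap (10% of genes would not overlap by chance with 3 against 3) and a named symbol, then up to 4 members per list with the smallest adjusted p, and a few fixed genes (Txnip, Arrdc4, Acta2, Col1a1, Col3a1, Postn, Igf2). Its application to the paired fit, where the same direction in 3 of 3 pairs replaced the non-overlap, was added after seeing the data.

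The 34 lists held functional groups, cell type markers and Y-linked genes. The functional lists were collagens, matrix glycoproteins, matrix remodelling, myofibroblast contractile genes, the TGF-beta pathway, cytokines and NF-kappaB targets, interferon response, glycolysis, targets of the carbohydrate-response element, polyol and hexosamine genes, oxidative stress, unfolded protein and amino acid stress, heat shock, cholesterol and fatty acid synthesis, fatty acid oxidation, osmotic response, cell cycle, senescence and p53 targets, fetal and imprinted growth genes, hypoxia, immediate early genes, the mitochondrial genome and the nuclear respiratory chain. The cell types were fibroblasts, cardiomyocytes, endothelium, macrophages, lymphocytes, smooth muscle, epicardium, Schwann cells, adipocytes and erythroid cells. Lymphocyte and erythroid lists had 0 of 10 and 0 of 6 members past the filter and were not tested. The other 32 were tested with camera (limma 3.58.1, preset correlation 0.01) in 9 comparisons, with adjustment over all 288 tests, and a second time with a correlation estimated per list. Tests of lists in the paired fit form a family of 160.

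Alternatives were DESeq2 1.42.0, median-ratio scaling, no filter, a fit to the compared groups only, limma-trend on log2 FPKM with 1 or 0.1 added, the pairs as blocks, and leaving out each library. For comparisons of ages, which share no pairs, the replicate number was instead added as a term common to all ages. Alternatives chosen after seeing the data were leaving out both 3-4 weeks libraries numbered 1, alternatives of the paired fit, leaving out each pair, and tests of 1 age against the mean of the others. The pipeline was tested on simulated data with 50 changed genes per fold. At 10-13 weeks the unpaired test found 6%, 40%, 78% and 96% of genes changed 1.25, 1.5, 2 and 4 fold, with 0 of 110 calls false. The paired test found 54%, 86%, 98% and 100%, with 7.7% of 183 calls false. These counts were simulated from the levels and spread of the paired fit, so pairing was built in. The gain over the unpaired test was thus fixed in advance and does not show that same-numbered libraries are pairs. The paired test of the mean effect found 4%, 22%, 84% and 96%, with 4.6% of 108 calls false. All these changes were put into the high glucose libraries of 10-13 weeks only. The figures for the mean effect thus cover a change at 1 age, and a change shared by the ages was not simulated.

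Total counts were 18874548 to 24654286 per library. A gene at 0 in a group was given a floor of 3 counts over the group, and folds against it are lower bounds that cover counting error only. Every library and every count column was used. Col1a2 and Hsp90aa1 are listed at 0 in all 24 libraries and were left out of their lists.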

Results

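Gene expression was measured by RNA sequencing in 24 libraries of cultured rat cardiac fibroblasts, the matrix-producing cells of the heart. They came from animals of 4 ages, with 3 libraries in normal glucose (5.5 mM) and 3 in high glucose (33 mM) at each age. Mean total counts per group, in M (mega-counts) for normal and high glucose, were 20 and 20.9 at 0-3 days, 19.3 and 20 at 3-4 weeks, 19.4 and 20.4 at 10-13 weeks, and 22.5 and 19.9 at 20 months. Single libraries had 18874548 to 24654286 counts. The 10 most abundant genes of a library took 10% to 12.3% of its counts, and 15188 to 15991 genes had a count. The first principal component of the log2 CPM values held 50.1% of the variance and ordered the groups by age, the second held 17.7% and the third 8%. Both 3-4 weeks libraries numbered 1 stood apart from the other 3-4 weeks libraries on each of these components. On the first they were at 12.7 and 12, against -6 to -1.4, and near the 10-13 weeks libraries (13.3 to 19.5). On the second they were at -7.7 and -7.8, against -30.4 to -25.3.

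Fibroblast markers summed to 6316 ± 319 CPM (SD, n = 3) at 0-3 days, 7095 ± 275 at 3-4 weeks, 7341 ± 330 at 10-13 weeks and 7700 ± 672 at 20 months in normal glucose. Cardiomyocyte markers were at 2531 ± 140 CPM at 0-3 days and at 214.3 ± 44.9, 176.1 ± 5.27 and 144.9 ± 7.24 CPM at the later ages. At the later ages the cardiac members Myh6, Myh7, Nppa, Ryr2 and Actc1 had 0 to 13 counts over each normal glucose group. Other members of the list made up these later sums. Macrophage and leukocyte markers were at 876.9 ± 131, 591.4 ± 357, 126.1 ± 35.6 and 145.3 ± 62.5 CPM. The 3-4 weeks libraries numbered 1 held 1003 CPM of them in normal and 1011 CPM in high glucose, against 363.8 to 433.5 CPM in the other 3-4 weeks libraries. Endothelial markers were at 163.6, 90.52, 104.8 and 77.8 CPM, and smooth muscle and pericyte markers at 2047, 2228, 1836 and 1397 CPM. Epicardial markers were at 114.1, 124.1, 130.7 and 175.6 CPM, Schwann cell markers at 20.53, 33.55, 25.37 and 67.87 CPM, and adipocyte markers at 376.9, 412.5, 351.3 and 577.7 CPM. Y-linked genes were at 169.1 ± 2.86, 163 ± 11.2, 160.8 ± 7.35 and 179.7 ± 6.71 CPM, and at 150.3 to 197.7 CPM over all 24 libraries. Lymphocyte markers reached at most 0.3593 CPM and erythroid markers at most 0.4211 CPM in any library. The marker sums differed between ages, so an age change of a gene may follow cell content. This was not separated from a change within fibroblasts. The mitochondrial share of counts was 4.63% ± 0.23 at 20 months in normal glucose, against 3.1% ± 0.091 at 0-3 days, 3.13% ± 0.21 at 3-4 weeks and 3.35% ± 0.23 at 10-13 weeks.

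**Figure D1:**
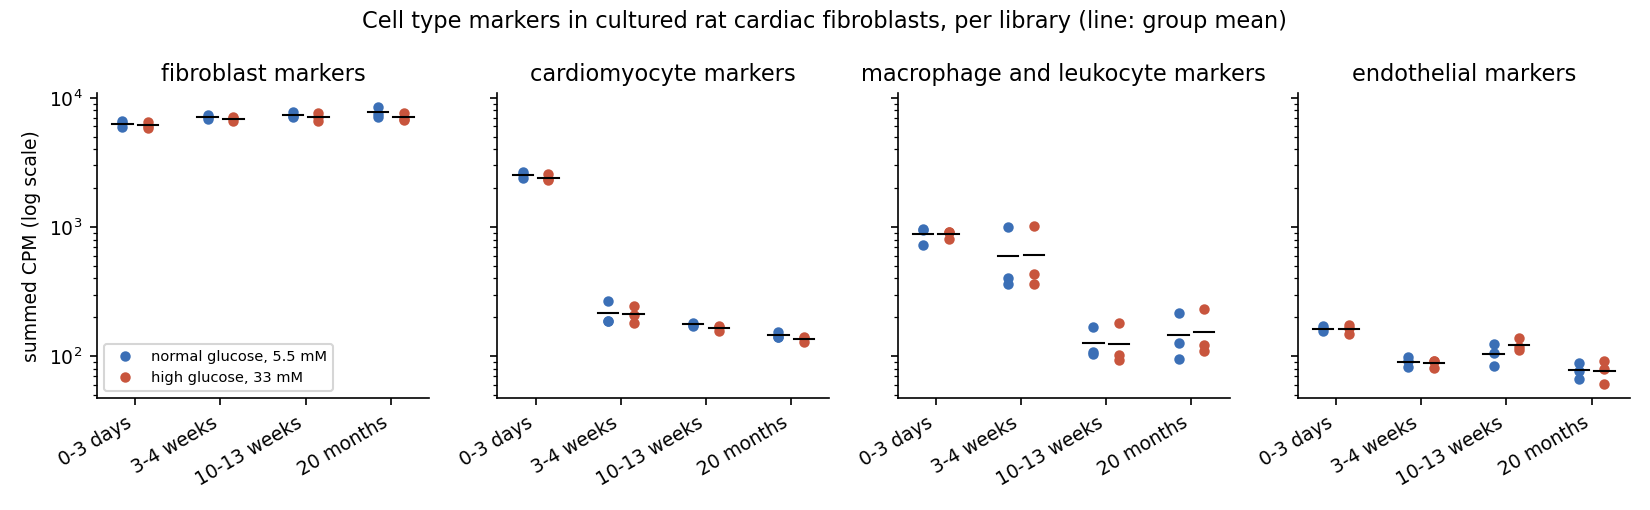
Summed CPM of the members of 4 marker lists (log axis) in each library (points) and as group means (lines), by age and glucose level. Cardiomyocyte markers had a mean of 2531 CPM at 0-3 days and 214.3 CPM or less in normal glucose at the later ages, and macrophage markers of the 3-4 weeks libraries numbered 1 reached 1003 and 1011 CPM.

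Between 0-3 days and 3-4 weeks in normal glucose, the comparison across the first weeks of life, 15 of 19 collagens rose and 17 of 18 cardiomyocyte genes fell. The collagens, of which 1 fell, had a median log2 change of 0.81. Col3a1, a fibrillar collagen (ENSRNOG00000003357, Rnor_6.0 chromosome 9, 52023295 to 52059217), went from 6050 ± 541 to 14180 ± 924 CPM (SD, n = 3; log2 change 1.23 ± 0.13 SE, adjusted p = 1.25e-06). Col1a1 rose from 19380 ± 1290 to 28590 ± 1720 CPM and Fbn1, the microfibril protein fibrillin, from 2031 ± 85.7 to 4841 ± 633 CPM. The surface antigen gene Thy1 went from 66.03 ± 3.76 to 248.7 ± 14.1 CPM (log2 change 1.91 ± 0.14, adjusted p = 3.44e-09). Among genes admitted by the naming rule the largest increase was that of Adh7, an alcohol dehydrogenase (4.27 ± 1.01, adjusted p = 0.00475). Of 25 genes of cholesterol and fatty acid synthesis 17 rose and 0 fell, with Scd1, a fatty acid desaturase, at 227.8 ± 43.9 against 73.3 ± 9.1 CPM (1.64 ± 0.27, adjusted p = 0.000207).

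Of 18 cardiomyocyte genes 17 fell, by a median log2 change of -7.8, or -7.05 with genes at 0 set to their bound. Actc1, cardiac actin (chromosome 3, 105507403 to 105512939), went from 523.4 ± 35.5 to 0.226 ± 0.21 CPM, and Myh6, the cardiac myosin heavy chain, from 471.2 ± 17.4 to 0.03495 CPM. Ryr2, the cardiac calcium release channel (chromosome 17, 65535403 to 65955606), had no count at 3-4 weeks and was at least 618-fold lower there. Of 16 fetal and imprinted growth genes 7 fell and 2 rose. Igf2, a fetal growth factor (ENSRNOG00000020369, chromosome 1, 215828102 to 215846911), went from 8.551 ± 0.841 to 0.2825 ± 0.294 CPM (log2 change -4.86 ± 0.63, adjusted p = 1.73e-05). The RNA-binding protein gene Igf2bp3 went from 21.95 ± 0.356 to 5.697 ± 1.3 CPM (-1.95 ± 0.19, adjusted p = 4.71e-07). Tnc, the matrix glycoprotein tenascin C, fell from 3891 ± 778 to 1031 ± 251 CPM. Of 17 contractile genes of myofibroblasts 8 fell and 1 rose, with Actg2 at 5.363 ± 2.36 against 42.15 ± 5.08 CPM and Acta2, smooth muscle actin, at 2592 ± 392 against 3539 ± 373 CPM. Of 27 cytokine and NF-kappaB genes 10 fell and 0 rose, including the chemokine gene Cxcl12 (-1.55 ± 0.38, adjusted p = 0.00542) and the complement gene C3 (-3.01 ± 0.71, adjusted p = 0.00452).

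In edgeR 3457 of 13806 genes passed the test, 1754 higher and 1703 lower at 3-4 weeks, and 1077 changed over 2 fold. Adjusted over the list alone, 15 collagens rose and 2 fell, 17 cardiomyocyte genes fell, 21 synthesis genes rose, 8 fetal genes fell and 2 rose, 8 contractile genes fell and 1 rose, and 11 cytokine genes fell. The list tests gave adjusted p = 2.39e-08 for collagens (adjusted p = 0.074 with an estimated correlation), 1.93e-189 for cardiomyocyte genes (adjusted p = 1.42e-13 with an estimated correlation), 9.52e-07 for synthesis genes (adjusted p = 0.709 with an estimated correlation). They gave 0.00303 for fetal genes (adjusted p = 0.0699 with an estimated correlation), 0.00303 for contractile genes (adjusted p = 0.567 with an estimated correlation) and 0.0165 for cytokine genes (adjusted p = 0.804 with an estimated correlation). Cell cycle genes had a median of -0.92 (adjusted p = 0.00541, and adjusted p = 0.911 with an estimated correlation) with 0 of 30 members called by edgeR over all genes or adjusted over the list alone. Of the marker lists, 6 of 11 endothelial genes fell (median -1.21, adjusted p = 0.0157, and adjusted p = 0.414 with an estimated correlation; 6 adjusted over the list alone). Of 10 smooth muscle genes 5 fell and 1 rose (median -1.6, adjusted p = 6.55e-05, and adjusted p = 0.284 with an estimated correlation; 6 and 1 adjusted over the list alone). Without the 0-3 days library numbered 2 in normal glucose the count of calls was 2289.

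From 3-4 to 10-13 weeks in normal glucose, 16 of 18 macrophage and leukocyte markers fell and 7 of 22 glycolysis genes rose. The macrophage markers had a median log2 change of -2.26. Among them were Adgre1, the macrophage antigen F4/80, from 3.307 ± 1.71 to 0.1392 ± 0.108 CPM (SD, n = 3; -4.5 ± 0.78 SE, adjusted p = 0.00262), and Ptprc, the leukocyte antigen CD45, from 13.32 ± 7.21 to 2.461 ± 0.733 CPM (-2.43 ± 0.38, adjusted p = 0.00134). Mpeg1, another macrophage gene (chromosome 1, 228724900 to 228727160), fell from 18.34 ± 10.9 to 1.486 ± 0.266 CPM. No glycolysis gene fell, and among those that rose was the lactate dehydrogenase gene Ldha at 739.6 ± 104 against 517.4 ± 21.8 CPM (0.52 ± 0.10, adjusted p = 0.00517). The glucose transporter gene Slc2a1 was at 97.86 ± 14.5 against 63.04 ± 6.94 CPM. Igf2bp3 fell further, to 1.172 ± 0.0232 CPM (-2.27 ± 0.23, adjusted p = 9.9e-06). The largest increase was that of RT1-CE16, a class I antigen gene (ENSRNOG00000047706, chromosome 20, 3791407 to 3794027), from 0.08463 ± 0.0788 to 42.66 ± 14.2 CPM (8.87, adjusted p = 3.66e-07). Class I genes have similar sequences and their reads are hard to part, and it overlaps RT1-A3, which was at 7.487 ± 1.99 against 0.05112 CPM, so the values of each are uncertain. Of 19 immediate early genes 3 rose (median 0.89), among them Fos (2.47 ± 0.64, adjusted p = 0.0342) and Dusp1 (1.05 ± 0.20, adjusted p = 0.00477), and Cyr61, a matrix protein gene, rose from 531.6 ± 56.8 to 1152 ± 255 CPM.

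In edgeR 496 genes passed the test, 153 higher and 343 lower, and 283 changed over 2 fold. With p adjusted over the list alone, 18 macrophage genes fell, 9 glycolysis genes rose and 5 immediate early genes rose. Their list tests gave adjusted p = 1.73e-32 (adjusted p = 0.0278 with an estimated correlation), 4.99e-08 (adjusted p = 0.229 with an estimated correlation) and 4.07e-06 (adjusted p = 0.498 with an estimated correlation). Smaller shifts passed for collagens (1 higher of 19, 2 adjusted over the list alone, median 0.14, adjusted p = 0.0195, and adjusted p = 0.604 with an estimated correlation). Matrix glycoproteins (1 higher of 23, 4 adjusted over the list alone, median 0.20) gave adjusted p = 0.0216, and adjusted p = 0.496 with an estimated correlation. Contractile genes (1 higher of 17, 4 adjusted over the list alone, median 0.21) gave adjusted p = 0.000185, and adjusted p = 0.449 with an estimated correlation. Interferon genes (1 lower of 28, 1 adjusted over the list alone, median -0.61) gave adjusted p = 0.00157, and adjusted p = 0.777 with an estimated correlation. Fetal genes (1 lower of 16, 4 lower and 1 higher adjusted over the list alone) had a median of -0.37, or -0.27 with bounds, and adjusted p = 0.0174, and adjusted p = 0.181 with an estimated correlation. Col1a1 (log2 change 0.06), Col3a1 (0.14) and Acta2 (0.28) did not pass. A fit to these 6 libraries alone called 94 genes, and leaving out the 10-13 weeks library numbered 2 left 228, the 3-4 weeks library numbered 1 left 270 and the 10-13 weeks library numbered 1 left 321. Without both 3-4 weeks libraries numbered 1, which held the most macrophage counts, 337 genes were called. The summed macrophage level was 1003 CPM in the 3-4 weeks normal glucose library numbered 1 and 406.6 and 364.7 CPM in the other 2 of that group, against 126.1 ± 35.6 CPM at 10-13 weeks. The list was not tested without that library.

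Between 10-13 weeks and 20 months in normal glucose, 30 of 30 cell cycle genes and 22 of 25 genes of cholesterol and fatty acid synthesis fell, while 8 of 11 mitochondrially encoded genes and 10 of 19 genes of senescence and p53 targets rose. The cell cycle genes had a median log2 change of -2.31. Mcm6, a replication helicase subunit (ENSRNOG00000003703, chromosome 13, 45042882 to 45068077), went from 134 ± 25.8 to 32.7 ± 10.7 CPM (SD, n = 3; -2.03 ± 0.37 SE, adjusted p = 0.000444). Of the senescence and p53 genes 3 fell. Cdkn2a, which encodes the inhibitor p16 (ENSRNOG00000059837, chromosome 5, 107823330 to 107841175), went from 6.374 ± 1.35 to 26.54 ± 6.72 CPM (2.06 ± 0.20, adjusted p = 7.4e-07). Cdkn2b, another inhibitor, went from 28.75 ± 17.9 to 144.5 ± 44.9 CPM, and Glb1, lysosomal beta-galactosidase, from 146.5 ± 8.99 to 248.9 ± 16.1 CPM. Of 25 synthesis genes 22 fell and 0 rose. Fasn, fatty acid synthase, was at 328.8 ± 50.8 against 739.8 ± 14 CPM.

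Of 19 collagens 11 fell and 2 rose: Col1a1 went from 29750 ± 2960 to 19920 ± 709 CPM and Col3a1 from 15670 ± 1630 to 8783 ± 317 CPM, while Col8a1 rose from 843.5 ± 25.4 to 1816 ± 353 CPM. Eln, elastin, fell from 430.9 ± 233 to 47.13 ± 16.6 CPM (-3.19 ± 0.57, adjusted p = 0.000401). Fn1, fibronectin, rose from 17160 ± 1260 to 28460 ± 3030 CPM and Acta2 from 3142 ± 298 to 4958 ± 222 CPM. Spp1, osteopontin (ENSRNOG00000043451, chromosome 14, 6673686 to 6679901), went from 39.16 ± 5.72 to 1258 ± 250 CPM (5.01 ± 0.40, adjusted p = 1.33e-07). Among genes admitted by the naming rule Acan, the cartilage proteoglycan aggrecan (ENSRNOG00000028992, chromosome 1, 140762758 to 140824441), rose most, from 0.16 ± 0.234 to 34.82 ± 9.92 CPM (7.73 ± 0.80, adjusted p = 2.21e-06). Among the same genes the growth factor gene Ptn fell most (-4.74 ± 0.69, adjusted p = 6.77e-05). Of 22 oxidative stress genes 9 rose and 1 fell, including Nqo1, a quinone reductase, from 138.2 ± 11 to 686.4 ± 193 CPM. Of 11 mitochondrially encoded genes 8 rose and 1 fell, with Mt-atp6 at 710.8 ± 78.6 against 233.8 ± 29 CPM, and these libraries had a higher mitochondrial share of counts. Of 22 glycolysis genes 11 fell and 1 rose, including Hk2, a hexokinase (-1.01 ± 0.13, adjusted p = 1.72e-05). Of 22 genes of unfolded protein and amino acid stress 12 fell and 1 rose, including the serine synthesis gene Psat1 (-1.58 ± 0.24, adjusted p = 0.000115). Of 19 immediate early genes 11 fell, including Myc (-1.35 ± 0.19, adjusted p = 4.93e-05), and of 28 interferon genes 7 fell, including Bst2 (-3.23 ± 0.69, adjusted p = 0.00145).

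In edgeR 4985 genes passed the test, 2478 higher and 2507 lower, and 1412 changed over 2 fold. Adjusted over the list alone, 30 cell cycle genes fell, 10 senescence genes rose and 3 fell, 23 synthesis genes fell, 11 collagens fell and 2 rose, 9 oxidative stress genes rose and 1 fell, and 8 mitochondrially encoded genes rose and 1 fell. On the same basis, adjusted over the list alone, 11 glycolysis genes fell and 1 rose, 14 stress genes fell and 3 rose, 11 immediate early genes fell, and 4 interferon genes fell. None of the list tests passed with an estimated correlation. Adjusted p was 3e-14 for cell cycle (adjusted p = 0.567 with an estimated correlation), 0.0112 for senescence (adjusted p = 0.449 with an estimated correlation) and 1.53e-11 for synthesis (adjusted p = 0.496 with an estimated correlation). The values were 0.000137 for collagens (adjusted p = 0.368 with an estimated correlation), 0.00345 for oxidative stress (adjusted p = 0.414 with an estimated correlation) and 1.31e-06 for mitochondrial genes (adjusted p = 0.284 with an estimated correlation). It was 0.00157 for glycolysis (adjusted p = 0.567 with an estimated correlation) and 0.00482 for unfolded protein and amino acid stress (adjusted p = 0.496 with an estimated correlation). For the rest it was 0.00259 for immediate early genes (adjusted p = 0.741 with an estimated correlation) and 0.0262 for interferon genes (adjusted p = 0.861 with an estimated correlation). Of the marker lists, 5 of 11 endothelial genes fell (5 adjusted over the list alone, median -0.97, adjusted p = 0.0382, and adjusted p = 0.496 with an estimated correlation). Of 6 Schwann cell genes 3 rose (3 adjusted over the list alone, median 0.82, adjusted p = 0.0174, and adjusted p = 0.414 with an estimated correlation). The glial gene S100b was at 15.23 ± 5.03 against 1.731 ± 0.392 CPM. Sox10, another glial gene, went the other way near the floor, with 7 counts over the group at 10-13 weeks and 0 at 20 months.

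Across the whole span, from 0-3 days to 20 months in normal glucose, 20 interferon, 30 cell cycle and 16 cardiomyocyte genes fell. Of 28 interferon genes 20 fell and 0 rose, by a median log2 change of -1.75. Macrophage and cardiomyocyte markers fell in the same comparison, so such falls are not separated from a change in cell content. Mx2, an antiviral GTPase (chromosome 11, 38035450 to 38059950), went from 22.39 ± 2.64 to 0.244 ± 0.275 CPM (SD, n = 3; -6.54 ± 0.93 SE, adjusted p = 1.34e-05) and Bst2, tetherin, from 95.57 ± 22.3 to 2.488 ± 1.14 CPM. Of 30 cell cycle genes 30 fell, with the spindle gene Tpx2 at 13.74 ± 4.95 against 149.5 ± 18.1 CPM. Aox1, an aldehyde oxidase (ENSRNOG00000015354, chromosome 9, 64929694 to 65007884), rose from 0.6567 ± 0.463 to 34.41 ± 6.89 CPM (5.72 ± 0.38, adjusted p = 1.15e-09). Gpx3, a secreted glutathione peroxidase, went from 184.6 ± 26.8 to 1560 ± 340 CPM, and Thy1 to 426.9 ± 82.5 CPM. Of 16 fetal genes 12 fell and 2 rose, with Igf2 at 0.668 ± 0.494 CPM (-3.65 ± 0.56, adjusted p = 2.3e-05) and Igf2bp1 at least 176-fold lower. Slc6a12, which encodes the osmolyte transporter BGT1, fell from 18.15 ± 4.09 to 0.2882 ± 0.305 CPM (-5.98 ± 0.69, adjusted p = 1.25e-06). Of the cardiomyocyte genes 16 of 18 fell (median -7.92, or -6.25 with bounds), and Myh6 was at least 10100-fold lower. Of 18 macrophage markers 15 fell (median -2.7). Of 19 senescence genes 12 rose and 2 fell, of 11 mitochondrially encoded genes 10 rose, and of 22 oxidative stress genes 10 rose and 4 fell.

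In edgeR 7438 genes passed the test, 3606 higher and 3832 lower, and 2761 changed over 2 fold. The median log2 change of all genes was -0.12 on FPKM with 1 added and -0.15 with 0.1 added, where the TMM-scaled counts gave 0, so the changes above are relative to the TMM scale. The counts adjusted over the list alone were 20 interferon, 30 cell cycle, 16 cardiomyocyte and 15 macrophage genes lower. On that basis 12 fetal genes fell and 2 rose, 12 senescence genes rose and 2 fell, 10 mitochondrially encoded genes rose, and 10 oxidative stress genes rose and 4 fell. List tests gave adjusted p = 4.76e-05 for interferon (adjusted p = 0.709 with an estimated correlation) and 6.14e-10 for cell cycle (adjusted p = 0.731 with an estimated correlation). Further values were 1.55e-89 for cardiomyocyte genes (adjusted p = 2.88e-11 with an estimated correlation), 0.00014 for fetal genes (adjusted p = 0.0216 with an estimated correlation) and 1.3e-05 for macrophage genes (adjusted p = 0.567 with an estimated correlation). They gave 0.00886 for senescence (adjusted p = 0.449 with an estimated correlation), 3.61e-05 for the mitochondrial genome (adjusted p = 0.414 with an estimated correlation) and 0.0305 for oxidative stress (adjusted p = 0.548 with an estimated correlation). Endothelial genes (7 lower and 1 higher of 11, 8 and 1 adjusted over the list alone, median -2.32) gave adjusted p = 0.0117, and adjusted p = 0.414 with an estimated correlation. Smooth muscle genes (6 lower of 10, 6 adjusted over the list alone, median -1.28) gave adjusted p = 0.0153, and adjusted p = 0.567 with an estimated correlation. The F tests of age over 4 ages called 8239 genes in normal and 8688 in high glucose. The genes with the smallest p in both were cardiac muscle genes, among them Actc1, Tnnc1, Nppa, Casq2, Myh7, Mybpc3, Myh6, Actn2 and Pln.

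**Figure D2:**
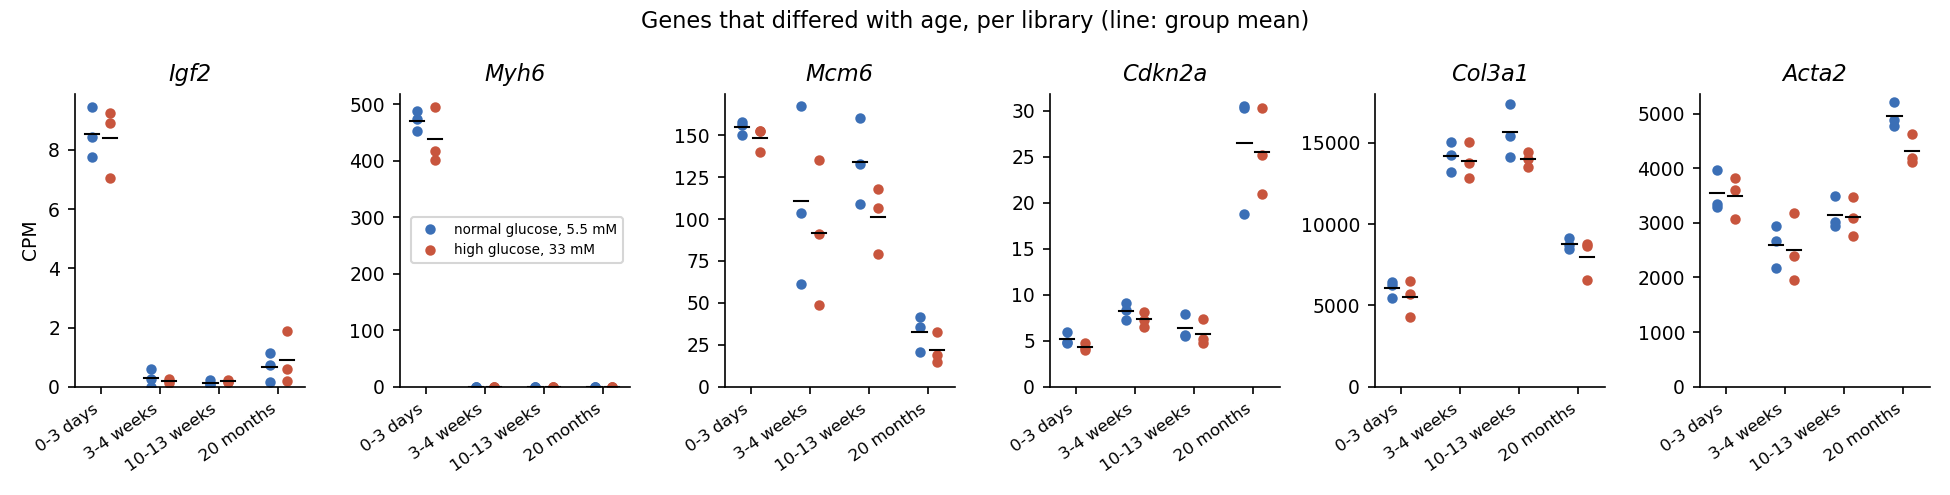
CPM (linear axis from 0) of 6 genes in each library (points) and as group means (lines), by age and glucose level. In normal glucose the mean of Mcm6 was 134 CPM at 10-13 weeks and 32.7 CPM at 20 months, and that of Cdkn2a 6.374 and 26.54 CPM.

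The next comparisons ask what 24 hours of high glucose changed at each age. The main, unpaired test called 0 genes at 0-3 days, 0 at 3-4 weeks, 1 at 10-13 weeks and 0 at 20 months. The genes named below for single ages come from the paired test unless stated otherwise. At 0-3 days, with cultures of the same number as pairs, 76 genes rose and 72 fell. Cyp1a1, a xenobiotic-metabolising oxygenase (ENSRNOG00000019500, chromosome 8, 62472095 to 62478147), was at 6.588 ± 0.877 CPM in high and 0.5508 ± 0.153 in normal glucose (SD, n = 3; paired log2 change 3.57 ± 0.50 SE, adjusted p = 0.0103). Tiparp, an ADP-ribosyltransferase (ENSRNOG00000011238, chromosome 2, 157316266 to 157341469), was at 45.35 ± 10.5 against 23.54 ± 3.06 CPM (0.93 ± 0.09, adjusted p = 1.42e-05). Ahrr, a repressor of the aryl hydrocarbon receptor, was at 17.73 ± 2.41 against 8.995 ± 0.79 CPM. Slco4a1, an organic anion transporter (ENSRNOG00000053430, chromosome 3, 175838994 to 175857983), was at 23.23 ± 2.61 against 9.408 ± 2.31 CPM (1.32 ± 0.15, adjusted p = 0.000247). Of 11 osmotic-response genes 3 rose. Slc6a12 (ENSRNOG00000013547, chromosome 4, 153921115 to 153941391) was at 32.38 ± 6.4 against 18.15 ± 4.09 CPM (0.84 ± 0.11, adjusted p = 0.00108). The taurine transporter gene Slc6a6 was at 153.2 ± 9.39 against 109 ± 17.7 CPM, and the amino acid transporter gene Slc38a2 at 708.4 ± 64.1 against 562.9 ± 6.82 CPM. Of 27 cytokine and NF-kappaB genes 3 rose, including Il6 (1.54 ± 0.28, adjusted p = 0.0122), Cxcl6 (1.54 ± 0.33, adjusted p = 0.0285) and Ptges, a prostaglandin synthase (1.06 ± 0.19, adjusted p = 0.00994). Of 22 oxidative stress genes 1 rose, Nqo1 (0.77 ± 0.13, adjusted p = 0.0278). Lyplal1, a lysophospholipase-like gene, fell (-0.87 ± 0.16, adjusted p = 0.00928), and the kinase gene Stk39 fell (-0.63 ± 0.11, adjusted p = 0.0056). Txnip (0.21) and Arrdc4 (0.23), both glucose-induced arrestin family genes, did not pass. In 3 of 3 pairs the summed epicardial (114.1 to 121.8 CPM), Schwann cell (20.53 to 24.94 CPM) and Y-linked levels (169.1 to 183.6 CPM) were higher, and cardiomyocyte (2531 to 2415 CPM), smooth muscle (2047 to 1966 CPM) and adipocyte levels (376.9 to 354.6 CPM) lower.

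The unpaired edgeR test called 0 genes at 0-3 days, with 522 at an unadjusted p under 0.05 and 5 by DESeq2; the smallest adjusted p, that of Tiparp, was 0.363. The paired test called 148 genes, 76 higher and 72 lower, 7 of them over 2 fold. Leaving out pairs 1, 2 and 3 gave 284, 16 and 28 calls, and the 6 libraries alone gave 21, 18 higher and 3 lower. When adjusted over the list alone, 5 osmotic genes rose, 5 cytokine genes rose, and 7 oxidative stress genes rose and 1 fell in the paired test, and 0 of each in the unpaired test. The unpaired list tests passed for osmotic genes (median 0.24, adjusted p = 0.000821, and adjusted p = 0.229 with an estimated correlation) and cytokine genes (median 0.34, adjusted p = 2.15e-06, and adjusted p = 0.496 with an estimated correlation). They also passed for oxidative stress genes (median 0.10, adjusted p = 0.00741, and adjusted p = 0.449 with an estimated correlation). For these 3 lists the paired tests gave 5.09e-09 (adjusted p = 0.062 with an estimated correlation), 7.28e-08 (adjusted p = 0.441 with an estimated correlation) and 3.09e-05 (adjusted p = 0.236 with an estimated correlation).

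At 3-4 weeks Slc6a12, Slco4a1, Slc38a2 and Slc38a4 were among 27 genes that rose in high glucose in the paired test. Slc6a12 was at 8.53 ± 5.07 against 3.845 ± 1.8 CPM (SD, n = 3; 1.12 ± 0.15 SE, adjusted p = 0.00232), and Slco4a1 at 7.745 ± 4.94 against 3.186 ± 1.47 CPM (1.24 ± 0.20, adjusted p = 0.0114). Slc38a2 was at 706.4 ± 111 against 524.5 ± 65.7 CPM (0.43 ± 0.05, adjusted p = 0.00124), and Slc38a4, another amino acid transporter, at 24.7 ± 6.27 against 16.14 ± 3.83 CPM. Tmod2, an actin-capping tropomodulin, fell from 4.01 ± 0.385 to 1.924 ± 0.414 CPM (-1.06 ± 0.21, adjusted p = 0.0275), and Timp3, a metalloproteinase inhibitor, fell (-0.61 ± 0.11, adjusted p = 0.0195). Of 30 cell cycle genes 1 fell, Mcm2 (-0.32 ± 0.06, adjusted p = 0.0195). Arrdc4 (0.41, adjusted p = 0.0835) and Txnip (0.23) did not pass. Summed fibroblast (7095 to 6894 CPM) and epicardial markers (124.1 to 111 CPM) were lower in 3 of 3 pairs. The paired test called 54 genes, 27 in each direction, and 21, 10 and 5 without pairs 1, 2 and 3. The unpaired edgeR test called 0, with 446 at an unadjusted p under 0.05 and 2 by DESeq2. Of the 11 osmotic genes 2 rose in the paired test, 4 rose and 1 fell adjusted over the list alone. The list had a median of 0.11, with adjusted p = 0.0165 unpaired (adjusted p = 0.449 with an estimated correlation) and 2.53e-06 paired (adjusted p = 0.0939 with an estimated correlation). Collagens (0 called of 19 by edgeR, 3 lower adjusted over the list alone) and cell cycle genes (5 lower adjusted over the list alone) passed as lists in the paired fit, with adjusted p = 0.00305 and 1.31e-05 (adjusted p = 0.713 and 0.508 with an estimated correlation).

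At 10-13 weeks the paired test found more genes changed by high glucose than at any other age. Inhba, a subunit of activin (ENSRNOG00000014320, chromosome 17, 51898217 to 51912496), rose from 307.3 ± 66.3 to 535.5 ± 65.6 CPM (SD, n = 3; 0.81 ± 0.10 SE, adjusted p = 0.00166). Ctgf, connective tissue growth factor, rose from 5272 ± 256 to 6569 ± 420 CPM (0.32 ± 0.06, adjusted p = 0.0026). The cytokine genes Il11 (1.24 ± 0.29, adjusted p = 0.0188) and Il6 (1.22 ± 0.30, adjusted p = 0.0229), the splicing factor gene Esrp2 (1.12 ± 0.17, adjusted p = 0.00107) and Slco4a1 (1.48 ± 0.27, adjusted p = 0.00346) rose over 2 fold. Adamts15, a matrix protease (ENSRNOG00000009892, chromosome 8, 31977001 to 32000378), fell from 13.59 ± 2.87 to 4.904 ± 1.04 CPM (-1.48 ± 0.14, adjusted p = 5.26e-05), and the endothelin receptor gene Ednra fell (-1.27 ± 0.27, adjusted p = 0.00689).

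Of 11 osmotic genes at 10-13 weeks 5 rose, with Slc38a2 at 754.6 ± 18.3 against 566.9 ± 7.22 CPM and Slc6a12 at 2.148 ± 1.19 against 0.9203 ± 0.656 CPM. Of 25 synthesis genes 8 fell and 0 rose, including Dhcr7, the last enzyme of cholesterol synthesis, at 55.05 ± 3.73 against 73.54 ± 3.05 CPM, and Srebf1, a regulator of lipid synthesis (-0.36 ± 0.06, adjusted p = 0.00166). Of 30 cell cycle genes 8 fell, including Mcm6 (-0.40 ± 0.07, adjusted p = 0.00191). Of 22 TGF-beta pathway genes Inhba, Skil and Id3 rose and Bambi, a pseudoreceptor, fell. Of 27 cytokine genes 4 rose and 2 fell, and of 22 glycolysis genes 2 rose (Hk2 and Slc2a1) and Pfkm fell. Arrdc4 (0.49 ± 0.10, adjusted p = 0.00649) and Txnip (0.27 ± 0.07, adjusted p = 0.0194) rose. Of the 10 epicardial markers 2 fell, Wt1 (-0.58 ± 0.13, adjusted p = 0.0106) and Aldh1a2 (-0.41 ± 0.07, adjusted p = 0.00187). The summed level of the epicardial markers went from 130.7 ± 15 to 98.96 ± 6.91 CPM and that of the Schwann cell markers from 25.37 ± 2.11 to 19.25 ± 2.2 CPM, lower in 3 of 3 pairs for each. Fibroblast (7341 to 7121 CPM) and cardiomyocyte markers (176.1 to 165 CPM) were lower in 3 of 3 pairs and endothelial markers higher (104.8 ± 20.1 to 122.7 ± 14 CPM). The cardiac genes Myh6, Myh7, Nppa, Ryr2 and Actc1 had 0 to 3 counts in each of these groups, so other members made up the cardiomyocyte sum. By chance 1 in 4 sums would move one way in 3 of 3 pairs. These sums use plain totals, and the TMM factors were lower in high glucose in each pair. They were 0.971, 0.973 and 0.939 in high and 0.99, 0.983 and 0.968 in normal glucose. Small falls such as that of the fibroblast markers may thus come in part from the scaling. The Schwann cell list did not pass (adjusted p = 0.262; paired 0.356). Log2 changes of Col1a1 (-0.13), Col3a1 (-0.16), Acta2 (-0.02) and Postn (-0.01) did not pass, and of 19 collagens 1 fell, Col6a1 (-0.19).

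The paired test called 1067 genes at 10-13 weeks, 586 higher and 481 lower, 49 over 2 fold, and 390, 706 and 150 without pairs 1, 2 and 3. On FPKM with 1 added, the paired limma test called 850 genes, 37.1% of them higher, against 54.9% in the paired edgeR test. The unpaired edgeR test called 1 gene, with 1174 at an unadjusted p under 0.05 and 35 by DESeq2. This gene, Smpd3, a sphingomyelinase gene, was outside the naming rule and chosen after its values were seen; it was at 0.0999 ± 0.0418 against 1.57 ± 0.568 CPM (-3.87, adjusted p = 0.00592; paired -3.90, adjusted p = 8.06e-05). Adjusted over the list alone, the paired test called 7 osmotic genes higher, 12 synthesis genes lower and 1 higher, 10 cell cycle genes lower, 6 TGF-beta genes higher and 1 lower, 5 cytokine genes higher and 2 lower, and 2 glycolysis genes higher and 1 lower. The unpaired test called 4 osmotic, 3 cytokine, 2 glycolysis and 2 immediate early genes higher adjusted over the list alone. The unpaired list tests passed for osmotic genes (median 0.41, adjusted p = 6.55e-05, and adjusted p = 0.128 with an estimated correlation) and synthesis genes (median -0.16, adjusted p = 0.00237, and adjusted p = 0.827 with an estimated correlation). They passed for cytokine genes (median 0.28, adjusted p = 0.00303, and adjusted p = 0.755 with an estimated correlation), immediate early genes (median 0.32, adjusted p = 0.00411, and adjusted p = 0.755 with an estimated correlation) and glycolysis genes (median 0.10, adjusted p = 0.0165, and adjusted p = 0.741 with an estimated correlation). Paired, these gave 1.92e-06 (adjusted p = 0.0939 with an estimated correlation), 8.25e-07 (adjusted p = 0.551 with an estimated correlation), 0.0224 (adjusted p = 0.741 with an estimated correlation), 0.0368 (adjusted p = 0.741 with an estimated correlation) and 0.0223 (adjusted p = 0.718 with an estimated correlation). The paired fit alone passed cell cycle (1.92e-06, and adjusted p = 0.448 with an estimated correlation) and TGF-beta genes (0.00662, and adjusted p = 0.441 with an estimated correlation).

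At 20 months 9 genes of cholesterol and fatty acid synthesis rose and 4 cell cycle genes fell in high glucose in the paired test. Of 25 synthesis genes 9 rose and 0 fell. Idi1, an isoprenoid synthesis enzyme (ENSRNOG00000016690, chromosome 17, 57976268 to 57984036), was at 100.4 ± 18.5 against 75.63 ± 16.8 CPM (SD, n = 3; 0.41 ± 0.06 SE, adjusted p = 0.00186). Insig1, a sterol sensor, was at 201.6 ± 44.6 against 152.1 ± 33.9 CPM, and Fasn at 418.1 ± 62.9 against 328.8 ± 50.8 CPM. Of 30 cell cycle genes 4 fell, including Mcm6 from 32.7 ± 10.7 to 22.18 ± 9.4 CPM (-0.58 ± 0.08, adjusted p = 0.00249). The replication origin gene Orc1 (-0.85 ± 0.16, adjusted p = 0.0123) fell. Of 11 osmotic genes 3 rose, with Slc6a6 at 261.4 ± 30.4 against 191.2 ± 31.2 CPM, Slc38a2 at 810.4 ± 138 against 617.4 ± 138 CPM, and Slc6a12 at 0.9727 ± 0.628 against 0.2882 ± 0.305 CPM. The glutathione synthesis gene Gclc (0.45 ± 0.07, adjusted p = 0.00949) and the cystine transporter gene Slc7a11 (0.39 ± 0.08, adjusted p = 0.0203) rose. Hspa5, an endoplasmic reticulum chaperone, fell (-0.23 ± 0.05, adjusted p = 0.0303), as did Timp3 (-0.60 ± 0.11, adjusted p = 0.0115). Txnip (-0.02), Arrdc4 (0.22), Acta2 (-0.20) and Col1a1 (-0.08) did not pass. The summed fibroblast (7700 ± 672 to 7064 ± 513 CPM), epicardial (175.6 to 154 CPM), cardiomyocyte (144.9 to 135.8 CPM) and smooth muscle markers (1397 to 1377 CPM) were lower in 3 of 3 pairs, and Y-linked genes higher (179.7 to 192.6 CPM). Myh6, Myh7, Nppa, Ryr2 and Actc1 had 0 to 5 counts in each of these groups, so other members made up the cardiomyocyte sum.

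The paired test called 128 genes at 20 months, 55 higher and 73 lower, 3 over 2 fold, and 13, 73 and 21 without pairs 1, 2 and 3. The unpaired edgeR test and DESeq2 called 0, with 452 at an unadjusted p under 0.05 in edgeR. Adjusted over the list alone, the paired test called 18 synthesis genes higher, 10 cell cycle genes lower, 3 osmotic genes higher, 6 stress genes lower, and 8 contractile genes lower and 1 higher, and the unpaired test 1 synthesis gene higher. Unpaired list tests passed for synthesis (median 0.24, adjusted p = 2.58e-11, and adjusted p = 0.496 with an estimated correlation) and osmotic response (median 0.12, adjusted p = 0.000798, and adjusted p = 0.229 with an estimated correlation). They passed downward for unfolded protein and amino acid stress (median -0.11, adjusted p = 0.00181, and adjusted p = 0.449 with an estimated correlation), contractile genes (median -0.11, adjusted p = 0.0286, and adjusted p = 0.741 with an estimated correlation) and cell cycle (median -0.18, adjusted p = 0.0461, and adjusted p = 0.924 with an estimated correlation). Paired, these gave 2.62e-28 (adjusted p = 0.197 with an estimated correlation), 2.73e-06 (adjusted p = 0.0939 with an estimated correlation), 3.09e-05 (adjusted p = 0.112 with an estimated correlation), 0.000634 (adjusted p = 0.441 with an estimated correlation) and 4.06e-10 (adjusted p = 0.397 with an estimated correlation).

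The mean effect asks what high glucose changed over the 4 ages together. Slco4a1 rose (log2 change 1.29 ± 0.27 SE, adjusted p = 0.0199; paired 1.27 ± 0.14, adjusted p = 6.37e-06; n = 12 per glucose level), as did Esrp2 (0.75 ± 0.11, adjusted p = 0.00152; paired adjusted p = 1.42e-05). Mtmr10, a myotubularin-related gene (0.50 ± 0.08, adjusted p = 0.0019; paired adjusted p = 2.61e-07), and Slc38a2 (0.39 ± 0.07, adjusted p = 0.0072; paired 0.39 ± 0.03, adjusted p = 3.85e-08) rose, as did Arrdc4 (0.33, adjusted p = 0.0278; paired 0.34, adjusted p = 0.000138). Lyplal1 (-0.69 ± 0.10, adjusted p = 0.00152; paired adjusted p = 5.5e-06), Tmod2 (-0.74 ± 0.11, adjusted p = 0.00152; paired adjusted p = 0.000154), Olfm1 (-0.58, adjusted p = 0.00275) and Ednra (-0.76 ± 0.19, adjusted p = 0.0396; paired adjusted p = 0.000243) fell. In the paired test Slc6a12 (1.24 ± 0.12, adjusted p = 4.81e-06; unpaired adjusted p = 0.0512), Slc6a6 (0.42, adjusted p = 1.14e-05), Gclc (0.35, adjusted p = 6.42e-06) rose. So did Il6 (1.08, adjusted p = 0.000175), Inhba (0.41, adjusted p = 0.000318), Spp1 (0.27, adjusted p = 4.81e-06) and Txnip (0.17, adjusted p = 0.00142). In the same test Mcm6 (-0.33, adjusted p = 6.37e-06), Timp3 (-0.44, adjusted p = 3.02e-05), Col1a1 (-0.08, adjusted p = 0.0276) and Col3a1 (-0.12, adjusted p = 0.0337) fell. Acta2 (-0.08, adjusted p = 0.109) and Postn (0.01, adjusted p = 0.799) did not pass. The paired test was passed by 5 osmotic genes of 11 upward, 15 cell cycle genes of 30 downward, 10 collagens of 19 downward, 6 cytokine genes of 27 upward, and 8 oxidative stress genes of 22 upward and 1 downward.

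The unpaired test called 218 genes for the mean effect, 85 higher and 133 lower, and the paired test 2490, 1138 higher and 1352 lower, 28 over 2 fold; all 218 were among the 2490, in the same direction. DESeq2 called 446 without pairs, and leaving out single libraries gave 103 to 336. Unpaired, 1 osmotic and 1 cytokine gene rose, and 4 and 3 adjusted over the list alone; paired, 7 osmotic, 6 cytokine and 8 oxidative stress genes rose and 17 cell cycle genes and 11 collagens fell adjusted over the list alone. The list tests passed unpaired for osmotic genes (median 0.16, adjusted p = 1.88e-06, and adjusted p = 0.0638 with an estimated correlation; paired 1.89e-10, and adjusted p = 0.062 with an estimated correlation). They passed as well for cytokine genes (median 0.22, adjusted p = 0.000173, and adjusted p = 0.681 with an estimated correlation; paired 0.00112, and adjusted p = 0.638 with an estimated correlation). Paired tests also passed for cell cycle genes (median -0.13, 5.09e-09, and adjusted p = 0.42 with an estimated correlation), collagens (-0.08, 0.00145, and adjusted p = 0.677 with an estimated correlation) and oxidative stress genes (0.06, 0.00632, and adjusted p = 0.441 with an estimated correlation).

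**Figure D3:**
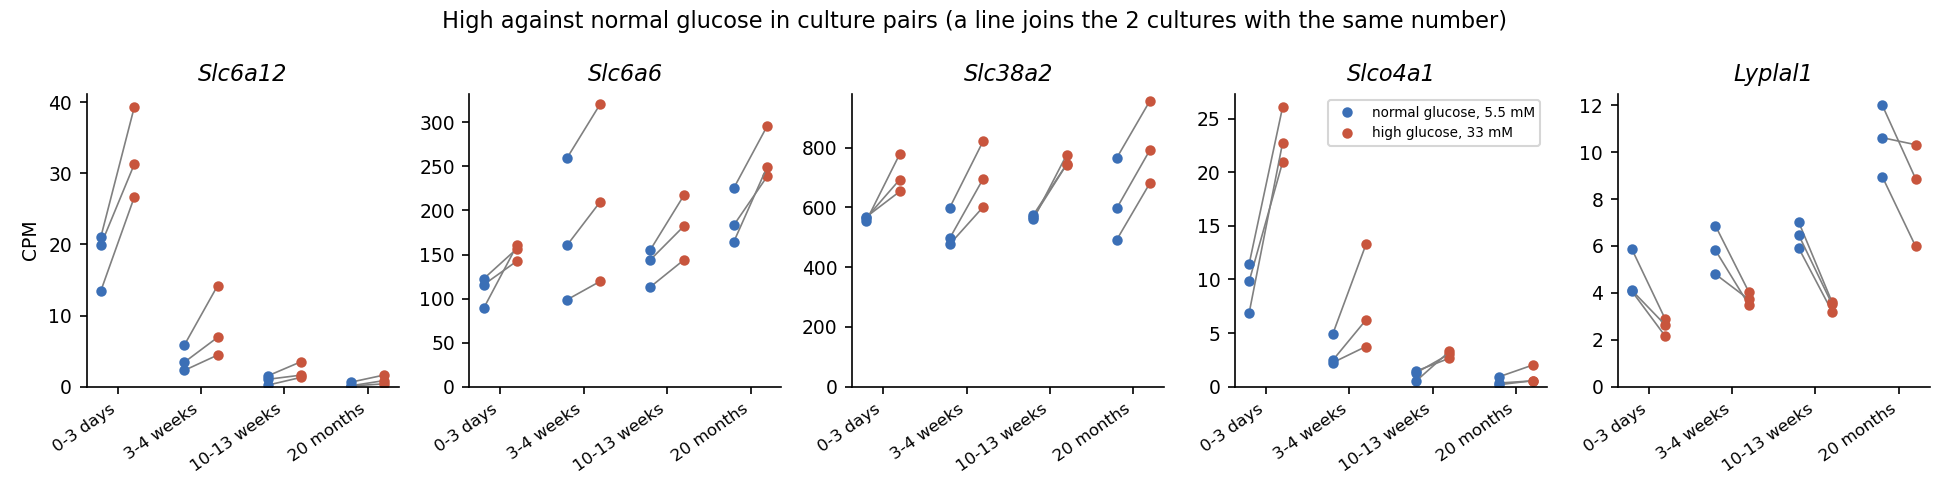
CPM (linear axis from 0) of 5 genes in each culture (points), by age, with a line joining the cultures of the same number and age in normal and high glucose. Slc38a2 was higher in high glucose in all 12 pairs, and its means rose from 562.9 to 708.4 CPM at 0-3 days and from 617.4 to 810.4 CPM at 20 months.

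Genes shared between ages were counted in the paired test. Mtmr10, Slc38a2 and Slc6a12 were called higher in all 4 ages, as were Acsl4, an acyl-CoA ligase gene, and Amd1, a polyamine synthesis gene, which with the tubulin gene Tubb3, lower in all 4 ages, were chosen after their values were seen. In 3 or more ages 16 genes were higher and 15 lower. Overlaps were larger than independent calls would give: 29 genes were higher at both 10-13 weeks and 20 months where 2.3 would be by chance, 38 were lower where 2.5 would be, and 0 went opposite ways. At 0-3 days and 10-13 weeks 29 were higher in both where 3.2 would be by chance, 22 were lower in both where 2.5 would be, and 9 went opposite ways, Ptges among them. The ages share a fit with the same spread per gene, so calls at 2 ages are not independent, which these chance values leave out. No chance value was computed for genes that went opposite ways. Across the 13806 genes, which are not independent replicates, the effects of 2 ages correlated at 0.1 to 0.22 (Pearson; Spearman 0.28 to 0.34), and across genes called in either age at 0.27 to 0.77.

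The interaction asks whether the glucose effect differed between ages, and its named genes come from the paired test. Creb3l1, a transcription factor gene of matrix secretion (ENSRNOG00000005413, chromosome 3, 80892435 to 80933283), had log2 changes of 0.60 ± 0.06 SE at 0-3 days, 0.01 at 3-4 weeks, -0.33 at 10-13 weeks and -0.02 at 20 months (n = 3 pairs each; interaction adjusted p = 0.000446). Tiparp had 0.93 ± 0.09 at 0-3 days and -0.05, 0.15 and 0.06 later (adjusted p = 0.00231). Adamts15 had -1.48 ± 0.14 at 10-13 weeks and 0.15, -0.20 and -0.09 at the other ages, in the order of age (adjusted p = 0.00231). Agtr1a, the angiotensin receptor (chromosome 17, 35907108 to 35958077), had -0.83 at 10-13 weeks and 0.15, -0.06 and -0.13 at the other ages (adjusted p = 0.00687). Of 25 cholesterol and fatty acid synthesis genes 9 were called for the interaction, each with its highest effect at 20 months. The list's own difference at 20 months had a median of 0.34 (adjusted p = 5.13e-59, and adjusted p = 0.139 with an estimated correlation). Examples were Fasn (adjusted p = 0.017), Idi1 (adjusted p = 0.0253) and Insig1 (adjusted p = 0.0307). Dhcr7 had -0.42 at 10-13 weeks and 0.23 at 20 months (adjusted p = 0.00818). The paired test called 46 genes, 93 with DESeq2 and 2 with limma on FPKM. The unpaired edgeR test and DESeq2 called 0, with 118 at an unadjusted p under 0.05 in edgeR. In that test Creb3l1, Trim72, Mettl15, Cyp1b1, Dtd1, Uqcc1, Rapgef4, Mbp, St7l and Tiparp had the smallest p values, each with an adjusted p of 1.

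**Figure D4:**
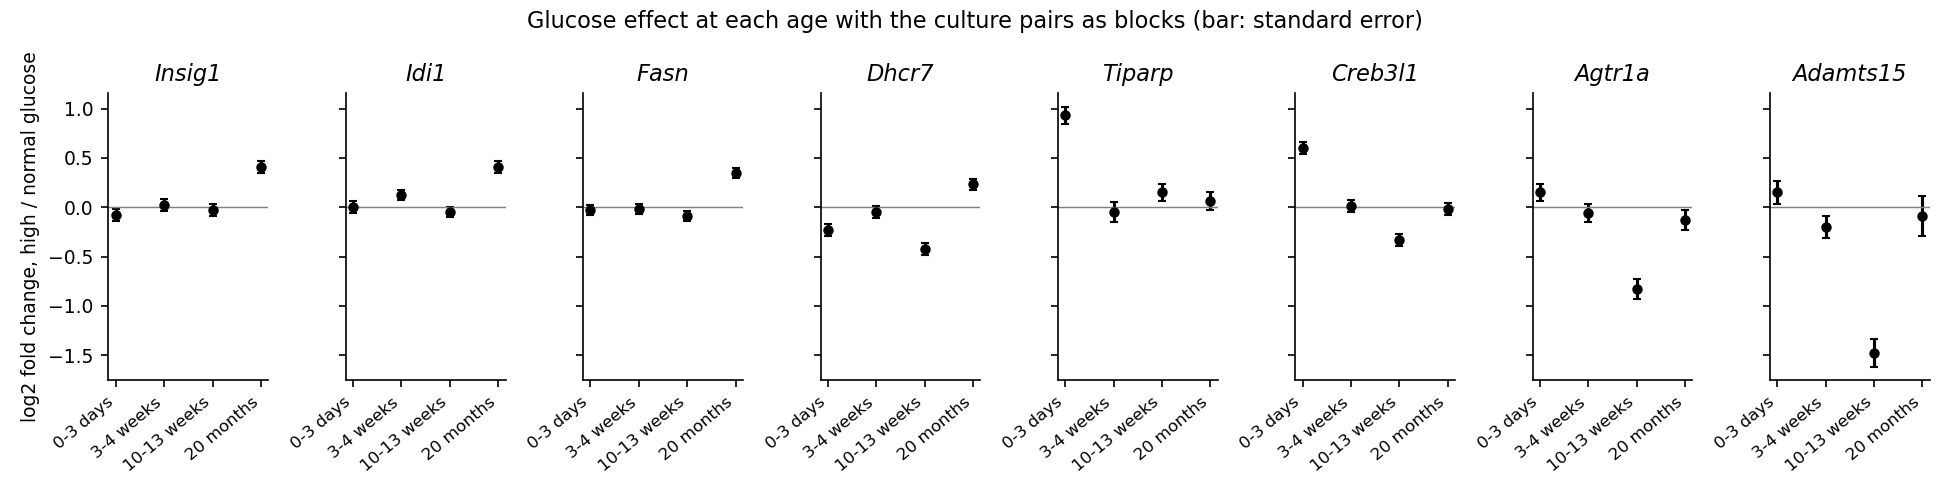
Paired log2 change in high over normal glucose at each age (points, with the standard error as bars) for 8 genes, chosen from those called for the interaction. Insig1 and Idi1 were at 0.41 at 20 months, Tiparp at 0.93 at 0-3 days, and Adamts15 at -1.48 at 10-13 weeks.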

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

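Tests of 1 age against the mean of the others, the alternatives of the paired test and the counts without a pair were chosen after the results were seen. The genes and lists in the next 2 paragraphs were singled out because their glucose effect passed a test of the difference between ages; the limits of these tests follow, and the count at 10-13 weeks was weighed without such a test.

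In the paired interaction test 46 genes differed between ages. Creb3l1 (adjusted p = 0.000446) and Tiparp (adjusted p = 0.00231) had their largest increase at 0-3 days. Kif26b, a kinesin gene (adjusted p = 0.00687), Tmcc3, a membrane protein gene (adjusted p = 0.00921), and Ackr3, an atypical chemokine receptor gene (adjusted p = 0.0124), were higher at 0-3 days, by 0.73, 0.48 and 0.72 on the log2 scale, and had values of -0.46, -0.50 and -0.43 at 10-13 weeks. Ptges (adjusted p = 0.01) had 1.06 at 0-3 days and -1.48 at 10-13 weeks. Adamts15 (adjusted p = 0.00231) and Agtr1a (adjusted p = 0.00687) were lower at 10-13 weeks. Fras1, a basement membrane gene (adjusted p = 0.00789), had -0.45 at 0-3 days, 0.45 at 10-13 weeks and 0.39 at 20 months, and Dhcr7 (adjusted p = 0.00818) had its only positive value at 20 months. Against the mean of the other ages, 20 genes differed at 0-3 days, 36 at 10-13 weeks and 11 at 20 months. At 3-4 weeks edgeR called 0, with 659 at an unadjusted p under 0.05, and no other tool was run on it.

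Cholesterol and fatty acid synthesis genes had a glucose effect at 20 months 0.34 above the mean of the other ages (median of 25 genes, adjusted p = 5.13e-59, and adjusted p = 0.139 with an estimated correlation), against -0.23 at 10-13 weeks and -0.11 at 0-3 days. Cytokine genes had 0.24 at 0-3 days and -0.26 at 20 months, and contractile genes -0.06 at 0-3 days, 0.15 at 10-13 weeks and -0.12 at 20 months. Cell cycle genes had 0.1 at 0-3 days and -0.08 at 20 months. At 0-3 days oxidative stress genes had 0.04 and epicardial markers 0.11. At 10-13 weeks TGF-beta pathway genes had 0.1 and interferon genes -0.13, and at 20 months genes of unfolded protein and amino acid stress had -0.07. With an estimated correlation none of these 15 list differences passed, the smallest adjusted p being 0.139.

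The paired test called 1067 genes at 10-13 weeks and at most 148 at another age. Mean totals at 10-13 weeks were 19.4 and 20.4 M, within the 19.3 to 22.5 M of the other ages, which argues against depth. The totals lay close together, so thinning could change little and adds little to this. With every library thinned to the smallest total, 10-13 weeks gave 1062 and the highest other age 144. A fit to its own 6 libraries gave 972 against 227 at another age, which argues against a spread borrowed from the other ages. Without pair 3, 10-13 weeks gave 150, under the 284 that 0-3 days gave without its pair 1, so the lead of this age may rest on a single culture pair. This sets its lowest count against the highest of another age. Without either other pair 10-13 weeks stayed above 284, and the lowest count of each other age was under 150. A difference in response with age stays open and was not tested apart from that.

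Other splits of the samples were counted for each test. For the mean effect 1 of 100 splits, the real one, gave as many genes (218 genes, highest other 89, and paired 1 of 100, 2490 and 973). The same held for age in normal (1 of 100, 8239 and 4761) and high glucose (1 of 100, 8688 and 4584). A chance arrangement of the libraries is thus unlikely for these, if the libraries are separate samples. For age the splits cannot part age from a preparation or batch that the libraries of an age may share. The paired interaction gave 7 of 100 (46, highest other 1478), so chance cannot be excluded there. Swapping labels within an age turns an effect shared by the ages into an interaction. Unpaired, the interaction had 0 genes in edgeR and DESeq2 (118 at an unadjusted p under 0.05 in edgeR, highest other 12). With a real count of 0 its share of 100 of 100 was fixed in advance and tests nothing. For the other comparisons the splits are too few for a share under 0.05. These gave 10 of 10 at 0-3 days (real 0, highest other 0), 10 of 10 at 3-4 weeks (0 and 630), 4 of 10 at 10-13 weeks (1 and 3) and 10 of 10 at 20 months (0 and 0). Where the real count was 0, the share of 10 of 10 was likewise fixed in advance. The edgeR counts at an unadjusted p under 0.05 were 522, 446, 1174 and 452, and DESeq2 called 5, 2, 35 and 0 in the same order. The split with 630 genes at 3-4 weeks parted 1 of 3 pairs and points to a structure of the samples, and the other splits that parted 3 pairs, as the real one does, gave 0 at each age. Swaps within pairs gave 1 of 4 at each age (148 and 16, 54 and 0, 1067 and 0, 128 and 0), and the 4 pairs of ages gave 1 of 10 each (3457, 496, 4985 and 7438, highest other 0).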

How the results depend on the processing

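Without both 3-4 weeks libraries numbered 1, the alternatives of the paired test, and leaving out pairs were tests chosen after the results were seen; the other alternatives were planned. None of the results tested reversed. Of 494 named results of genes, 385 passed under each alternative run and 109 lost the call under at least 1. Of 294 named results of the paired test, 22 passed under each alternative and 271 lost the call without the pairs. DESeq2 and RLE scaling kept all 494 calls, and limma on FPKM with 1 added lost 26.

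In high glucose at 0-3 days, where edgeR called 0, DESeq2 called 5, the 6 libraries alone 3, the paired test 148, and the fit without both 3-4 weeks libraries numbered 1 called 1. At 3-4 weeks, where edgeR called 0, these were 2 with DESeq2, 54 paired and 1 without both libraries. At 10-13 weeks, where edgeR called 1, they were 35 with DESeq2, 0 on its own libraries, 1067 paired, 0 with limma on FPKM with 1 added, and 3 without both libraries. Leaving out single libraries there gave 0 to 1, with 0 without replicate 3 in normal glucose or any 1 of the 3 in high glucose. At 20 months, where edgeR called 0, the paired test called 128. The mean effect (218) gave 446 with DESeq2, 2490 paired and 132 without both libraries. Leaving out single libraries gave 103 to 336: at 0-3 days 138 and 144 without replicates 1 and 3 in normal glucose, and 336, 103 and 111 without replicates 1, 2 and 3 in high glucose; 145 without replicate 2 at 10-13 weeks in normal glucose; and at 20 months 135 without replicate 1 in normal and 133 without replicate 3 in high glucose. The interaction (0) gave 46 paired. The cause was not tested, apart from the pairs, which take out the variation that same-numbered cultures share.

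From 0-3 days to 3-4 weeks leaving out single libraries gave 2289 to 3865, with 2289 without replicate 2 at 0-3 days. From 3-4 to 10-13 weeks it gave 228 to 469: 270 without replicate 1 at 3-4 weeks, and 321 and 228 without replicates 1 and 2 at 10-13 weeks. The 6 libraries alone gave 94, where fewer samples estimate the spread. Age in normal glucose gave 7328 to 8568 and in high glucose 7830 to 8957 with single libraries left out. Where an arm kept 2 libraries the fit pooled the spread. On FPKM with 1 added 1262 genes rose and 2735 fell from 0-3 days to 3-4 weeks, against 1754 and 1703 in edgeR, and 2515 rose and 5112 fell from 0-3 days to 20 months, against 3606 and 3832. FPKM leaves out the TMM factors, which lowers the later age by construction: in normal glucose these were 1.06 to 1.07 at 0-3 days, 1 to 1.02 at 3-4 weeks and 0.94 to 0.968 at 20 months.

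Paired results were more sensitive. At 0-3 days (148) they gave 21 on the 6 libraries (18 higher and 3 lower), 0 without pairs, and 16 to 284 with a pair left out (284, 16 and 28 without pairs 1, 2 and 3). At 3-4 weeks (54) limma on FPKM gave 21, no pairs 0, and leaving out a pair 5 to 21 (21, 10 and 5). At 10-13 weeks (1067) no pairs gave 1, and leaving out a pair 150 to 706 (390, 706 and 150). At 20 months (128) its own libraries gave 227, limma 60, no pairs 0, and leaving out a pair 13 to 73 (13, 73 and 21). The mean effect (2490) gave 218 without pairs and 1948 to 2800 with a pair left out. The interaction (46) gave 93 with DESeq2, 2 with limma and 0 without pairs. Leaving out a pair gave 8 to 86: 86, 18 and 8 without pairs 1, 2 and 3 at 0-3 days, 26 and 24 without pairs 2 and 3 at 3-4 weeks, 16 and 18 without pairs 1 and 3 at 10-13 weeks, and 12 without pair 1 at 20 months. Counts of 0 without pairs are those of edgeR given above. With a pair left out 2 pairs remain at that age, which widens the error and would lower counts. Some counts rose instead, as from 148 to 284 at 0-3 days and from 46 to 86 for the interaction. The cause was not tested.

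Of 55 list results, 4 passed with an estimated correlation and 55 with the replicate number in the fit. That number stood for pairs within an age only in the 16 glucose results. In the age comparisons it was a term common to all ages, so they were not tested with pairs. Of the 16 in glucose comparisons, 0 passed with an estimated correlation in camera (7 at an unadjusted p under 0.05). In their own family of 160 tests, the paired list tests passed 34, where the unpaired ones passed 16 of the same comparisons and lists. Correlations of glucose effects between ages were 0.66, 0.37, 0.27, 0.64, 0.77 and 0.55 over genes called in either age, in the order 0-3 days with 3-4 weeks, 10-13 weeks and 20 months, 3-4 weeks with 10-13 weeks and 20 months, and 10-13 weeks with 20 months, against 0.22, 0.15, 0.12, 0.18, 0.1 and 0.16 over all genes. Genes chosen for a large effect raise such a correlation by construction. A fit to the groups compared was not applicable to the mean effect and the interaction, which use all 24 libraries. Depth of 18874548 to 24654286 counts limits genes of few counts, and 3 samples per group limit small changes. The smallest simulated changes were put into 10-13 weeks only, in data with the fitted pair levels built in. Of these changes 6% were found unpaired and 54% paired at that age. The paired test of the mean effect, which averages them with the unchanged ages, found 4%. A change shared by the ages was not simulated, so this share is no limit for such a change.

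From 3-4 to 10-13 weeks in normal glucose, Adgre1, Mpeg1 and Ptprc also fell without the normal glucose library numbered 1 of 3-4 weeks, each by less than with it.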

Other observations

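The test of class I genes summed together and the count of osmotic control groups were tests chosen after the result was seen. Of genes whose levels are given nowhere above, the glial myelin gene Mbp rose from 21.01 ± 2.42 CPM at 10-13 weeks to 52.18 ± 3.44 CPM at 20 months (SD, n = 3, log2 change 1.31 ± 0.12 SE, adjusted p = 4e-07). The neuropeptide precursor gene Trh rose from 1.209 ± 0.535 to 27.72 ± 12.9 CPM between the same ages (4.51 ± 0.52, adjusted p = 6.36e-06). Foxa2, an endodermal transcription factor gene (ENSRNOG00000013133, Rnor_6.0 chromosome 3, 142383278 to 142387481), rose from 0.3183 ± 0.176 CPM at 0-3 days to 18.9 ± 4.15 CPM at 20 months (5.88 ± 0.59, adjusted p = 2.54e-07). The fibroblast receptor gene Pdgfra fell from 200.1 ± 17.3 to 65.22 ± 12.5 CPM between 10-13 weeks and 20 months (-1.62 ± 0.32, adjusted p = 0.000961). Igf2 rose from 0.1233 ± 0.0828 to 0.668 ± 0.494 CPM there (2.41 ± 0.89, adjusted p = 0.0402).

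Lists that passed in none of the 9 unpaired comparisons had these smallest adjusted p values. Matrix remodelling genes had 0.23 from 0-3 days to 3-4 weeks (7 higher and 4 lower of 24, 9 and 7 adjusted over the list alone, median 0.08), fibroblast markers 0.0564 in the same comparison (5 higher and 1 lower of 14, the same adjusted over the list alone, median 0.22), and hypoxia genes 0.153 from 3-4 to 10-13 weeks (2 higher and 1 lower of 16, median 0.15). Adipocyte markers had 0.158 there (median -0.98 of 3), and polyol and hexosamine genes 0.11 from 0-3 days to 20 months (7 higher and 1 lower of 14, median 0.45). In high glucose at 10-13 weeks TGF-beta genes had 0.0841 (median 0.06), heat shock genes 0.199 (0.09), fatty acid oxidation genes 0.153 (-0.12) and epicardial markers 0.0761 (-0.34). Targets of the carbohydrate-response element had 0.0845 in high glucose at 3-4 weeks (0.07), nuclear respiratory chain genes 0.12 at 20 months (-0.04), and Y-linked genes 0.0534 at 0-3 days (0.14).

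The paired tests alone also passed epicardial markers (adjusted p = 0.00815, and adjusted p = 0.235 with an estimated correlation), interferon genes (adjusted p = 0.0197, and adjusted p = 0.42 with an estimated correlation) and collagens (adjusted p = 0.0266, and adjusted p = 0.741 with an estimated correlation) at 10-13 weeks, all downward. At 20 months they passed targets of the carbohydrate-response element upward (adjusted p = 0.0492, and adjusted p = 0.448 with an estimated correlation). Median, mean and test differed in sign for some lists that did not pass. From 0-3 days to 20 months epicardial markers had a median of 0.49 and a mean of -0.28, osmotic genes 0.08 and -0.64, and Schwann cell markers 1.06 and -0.02. Fibroblast markers had 0.14 and -0.46 from 10-13 weeks to 20 months.

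Osmotic-response genes had a median paired effect of 0.16 over 11 genes, of which 5 were called higher (adjusted p = 1.89e-10, and adjusted p = 0.062 with an estimated correlation). No trend with gene length of that size was seen, since the fitted trend ran from -0.02 to 0.03 over the tested genes. With so flat a trend taken off the median stayed at 0.16, which by itself is no further test. The effects of the 11 list members had an SD of 0.34. The design holds 0 osmotic control groups, so osmolarity of the medium and glucose itself cannot be told apart as the source, and either may raise Slc6a12, Slc6a6 and Slc38a2. No biological explanation was tested.

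Class I antigen genes changed apart from each other between 3-4 and 10-13 weeks in normal glucose: 6 of 20 tested rose, up to 8.87 on the log2 scale for RT1-CE16, and 2 fell, by 2.03 at most. Of these, 3 rose and 0 fell by over 3 on the log2 scale. Higher antigen presentation as a whole is argued against, since 8 other genes of that pathway had a median of -0.39 (-1.13 to 0.13); edgeR called 0 of them, and the smallest adjusted p was 0.159. Macrophage and leukocyte markers, from cells that also present antigen, fell in the same comparison (591.4 ± 357 to 126.1 ± 35.6 CPM), so the pathway genes do not show what the fibroblasts alone did. The summed class I level had a log2 ratio of -0.01 (359.8 ± 35.3 against 363.5 ± 122 CPM, n = 3). An unchanged sum may come from reads split between similar genes or haplotypes. The test for that also looked for falls of over 3 on the log2 scale and found 0. An abundant gene can lose many counts with a smaller log2 fall, so the test does not settle the question. RT1-A2, the most abundant class I gene at 3-4 weeks, went from 125.2 ± 43.4 to 45.61 ± 11.5 CPM (log2 change -1.46, adjusted p = 0.00517). Split reads and changes of single genes cannot be told apart here, because the table holds counts per gene and no sequence. A difference with age stays open and was not tested, and the labels give no strain or passage number at each age.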
